A study of Mus musculus with 6 samples.

How the data were processed

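Total RNA was extracted from macrophages sorted by flow cytometry out of subcutaneous MC38 tumours, and libraries were made with a TruSeq kit after ribosomal RNA depletion, per the labels' protocols. The markers of the sorting gate are not given in the sources used here. The 6 libraries, each from 1 mouse, were grouped by genotype and clone as the labels give them.

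The deposited table holds estimated counts per gene symbol, as whole numbers that are not scaled to library size. Salmon 0.7.2 and the assembly mm10 are named in the submitters' processing notes, without a role or order. The transcript set, the filters and the step from transcripts to genes are not given in the sources used here. Values of 7 digits or more carry 6 significant digits, as Salmon writes its estimates. How reads shared between near-identical genes such as Ly6c1 and Ly6c2 were divided is not stated, so such genes are uncertain one by one. Whether strand was used is not stated either. No mitochondrially encoded gene is listed under the symbols searched. Of the 21760 symbols, 20429 (93.9%) matched a gene name of GENCODE M21 on GRCm38, from which positions were taken, and 235 had no count in any library.

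Library totals were 20038047 for WT mouse 2 and 37090034 to 40022755 for the other 5. Each library was counted as a separate sample because the labels give separate mice. The 2 libraries of each group were not copies of each other, with a chi-square per degree of freedom of 85.6 to 924 against counting noise. Rn45s stayed in the table for the main analysis.

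Genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test after filterByExpr with its default minimum count of 10 and minimum total of 15, and with TMM factors. KO was compared with WT in a fit with 2 genotype levels, so that the difference between clones counts as spread. All KO mice entered as replicates, although mice with tumours of the same clone are not independent units of the knockout. Loss of Xkr8 cannot be told apart from other traits that the clones share. Each clone against WT, and clone 2 against clone 1, came from a fit with 3 groups that share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its absolute value divided by the square root of F. The biological coefficient of variation was 0.297 in the fit by genotype. Levels are CPM on TMM-scaled library sizes, computed from the deposited counts.

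Before the data were examined, 38 gene lists were fixed for pathways, macrophage states and markers of other cell types, and 37 had at least 5 tested members. They were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists, and again with an estimated correlation. List symbols absent from the table were matched through older symbols where a single match existed. The level of a list in a library is the mean log2 CPM of its members.

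Genes named singly followed a rule fixed before the data were examined. In KO against WT these are the 10 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM and all KO libraries on the same side of both WT libraries, predicted gene models left out. Where a direction had none, the 5 genes with the smallest p were taken and are said not to have passed. The clone contrasts took 5 in each direction by the same criteria. Within lists up to 4 members per direction with the smallest p could be named, and 15 macrophage genes were reported whatever their result. A gene that the rule allows is not reported here. Outside this rule, the remaining calls between genotypes (Mfap4 among them), Ctla4 and Tgtp1 by clone, and single members of the second lists were named after their values were seen.

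The correlation of the clones' fold changes was set beside 100 simulations of unchanged groups that share simulated WT libraries, all drawn from the same mean and spread per gene. The fits were tested on simulated counts drawn from the means and library sizes of these libraries with 200 changed genes. For KO against WT over 15343 genes, 4 of 50 genes with a log2 change of 1 were recovered, 37 of 50 with 2, 43 of 50 with 3 and 48 of 50 with 4. Of 137 calls there, 5 were of unchanged genes. That count was 8 of 129 for clone 1 against WT, 5 of 112 for clone 2 against WT and 14 of 138 between clones. A simulated list of 25 changed genes was recovered by camera with both kinds of correlation for KO against WT. Between clones it was recovered with the preset correlation but not with an estimated one (adjusted p = 0.0797). The simulated genes were drawn independently of each other, so this does not show how camera behaves on lists whose members vary together.

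Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of at least 5 CPM in at least 2 libraries, the mouse number as a block, a table without Rn45s, the mean of the clones in the fit with 3 groups, and leaving out each library. After the data had been seen, limma-voom with sample quality weights and leaving out each library in the list test between clones were added. GC content and length of the longest transcript of each gene were read with Biostrings 2.70.1 from GENCODE M21 for 14910 of the tested genes (95.8%).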

Results

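RNA sequencing was used to profile macrophages sorted by flow cytometry from MC38 tumours, which grow from a mouse colon carcinoma line. The tumours had grown for 16 days under the skin of C57BL6 mice. Tumours were either wild type (WT) or knocked out (KO) for Xkr8, a scramblase that caspases activate and that brings phosphatidylserine to the outer face of dying cells. Phosphatidylserine on a dying cell is a signal that macrophages recognise. The comparison asks how the macrophages of a tumour differ when its cells are blocked in this exposure. There were 2 WT libraries, 2 libraries from KO clone 1 and 2 from KO clone 2, each from a separate mouse.

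Library totals ran from 20038047 to 40022755 estimated reads over 21760 gene symbols. WT mouse 2 stood apart from the other 5 libraries. Its total was the lowest, against 37090034 to 40022755 in the others, and the 45S pre-ribosomal RNA Rn45s took 24.6% of it against 1.46% to 7.12%. It had counts for 16810 symbols, against 18193 to 19250 in the others. Pearson correlations of log2 CPM with the other libraries were 0.912 to 0.927 for WT mouse 2 and 0.972 to 0.989 among the other 5.

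**Figure D1:**
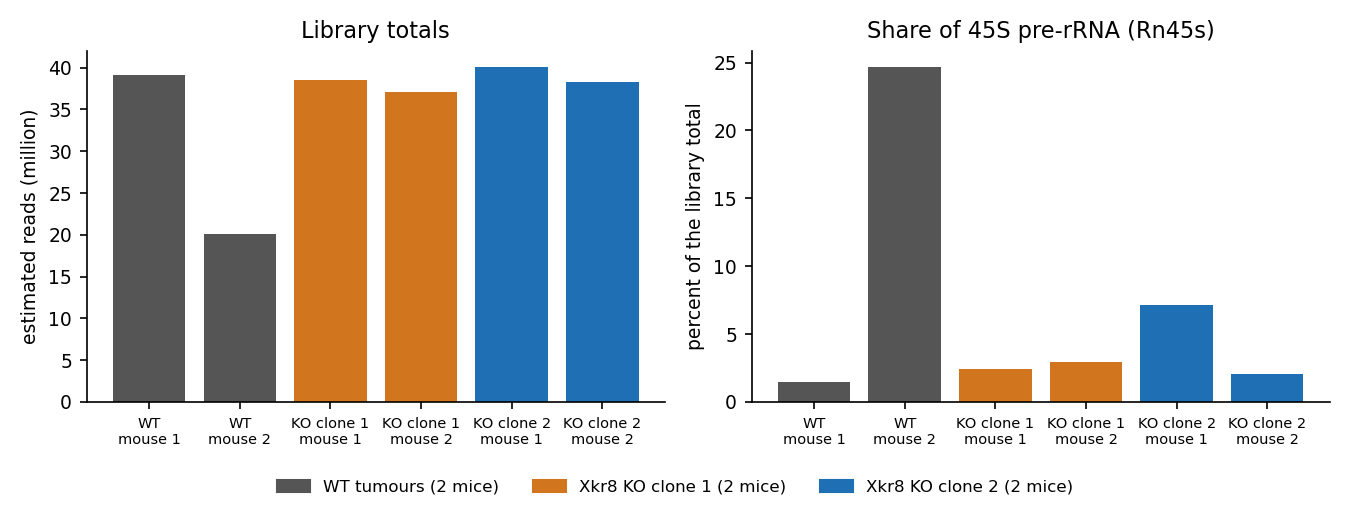
Bars show, for each of the 6 libraries, the total of estimated reads (left) and the percent of that total assigned to Rn45s (right), coloured by group. WT mouse 2 has the lowest total, with 24.6% of it from Rn45s.

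The knockout was made in the tumour, so the level of Xkr8 in host macrophages does not check the labels. Xkr8 stood at 5.49 ± 1.30 CPM (SD, n = 4) in macrophages from KO tumours and 6.48 ± 0.60 CPM (SD, n = 2) in those from WT tumours. Its log2 fold change was -0.24 ± 0.27 (SE), with an adjusted p of 0.637. The macrophage genes Adgre1 (F4/80) and Csf1r (the CSF1 receptor) were abundant in both genotypes. Adgre1 averaged 886 ± 90.6 CPM (SD, n = 4) in KO and 598 ± 98.2 CPM (SD, n = 2) in WT libraries. Csf1r averaged 1228 ± 114 and 1373 ± 367 CPM. Neither difference passed the test, with adjusted p of 0.324 and 0.692.

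Among the genes that passed between macrophages of KO and WT tumours, Ly6c2, a surface marker of inflammatory monocytes, had the smallest p. Ly6c2 averaged 90.4 ± 6.76 CPM (SD, n = 4) in KO and 3.49 ± 1.09 CPM (SD, n = 2) in WT libraries, a log2 fold change of 4.72 ± 0.27 (SE) and an adjusted p of 0.00279. The related gene Ly6i rose by 3.64 ± 0.34. Genes known from T and NK cells rose as well. They were Cd3g, a chain of the T cell receptor complex (3.82 ± 0.39), the inhibitory receptors Ctla4 (3.47 ± 0.26) and Pdcd1 (3.16 ± 0.29), the adhesion molecule Cd2 (2.70 ± 0.31), the activating receptor Klrk1 (2.63 ± 0.23) and the lymphocyte GTPase Gimap4 (3.06 ± 0.33). Tgtp1, a GTPase induced by interferon-gamma, rose by 2.64 ± 0.24, and the glycosyltransferase B3gnt5 by 2.76 ± 0.30. The adjusted p of these 9 genes lay between 0.0106 and 0.0327.

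Over 15560 genes tested with edgeR's quasi-likelihood test, 20 were higher and 1 was lower in KO libraries. The other 10 higher genes were Slfn1, Ms4a4c, Ifit1bl1, Upp1, Gimap7, Gimap6, Cd226, Ly6a, Cfb and Dpp4, and the lower gene was Mfap4, which encodes a microfibril protein. Mfap4 averaged under the mean level set for named genes and had a log2 fold change of -2.35 ± 0.28. Among genes above that level, the smallest p for a lower value belonged to Nid2, a basement membrane protein, at -1.35 ± 0.19 with an adjusted p of 0.0561. Kif26b (-2.38 ± 0.43), Rtn1 (-1.39 ± 0.26), the carbonic anhydrase Car9 (-1.36 ± 0.26) and Tyr (-1.21 ± 0.23) followed and did not pass either.

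Ly6c2 lies on chromosome 15 from 75108158 to 75111970 on the minus strand (GRCm38, GENCODE M21), and Ly6i in the same gene cluster from 74979534 to 74983430. Ly6c2 has a near-identical neighbour, Ly6c1, so the split of reads between them is uncertain. Their summed level was 19.0 and 16.8 CPM in the WT libraries and 98.2 to 129 CPM in the KO libraries. Tgtp1 (chromosome 11, 48985327 to 48994172) has the near-copy Tgtp2. Tgtp1 and Tgtp2 together stood at 103 and 72.2 CPM in WT and 272 to 381 CPM in KO libraries. Ctla4 (chromosome 1, 60887000 to 60915832), Pdcd1 (chromosome 1, 94038305 to 94052553), Cd3g (chromosome 9, 44969572 to 44980431) and Klrk1 (chromosome 6, 129610323 to 129623864) are protein-coding genes.

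**Figure D2:**
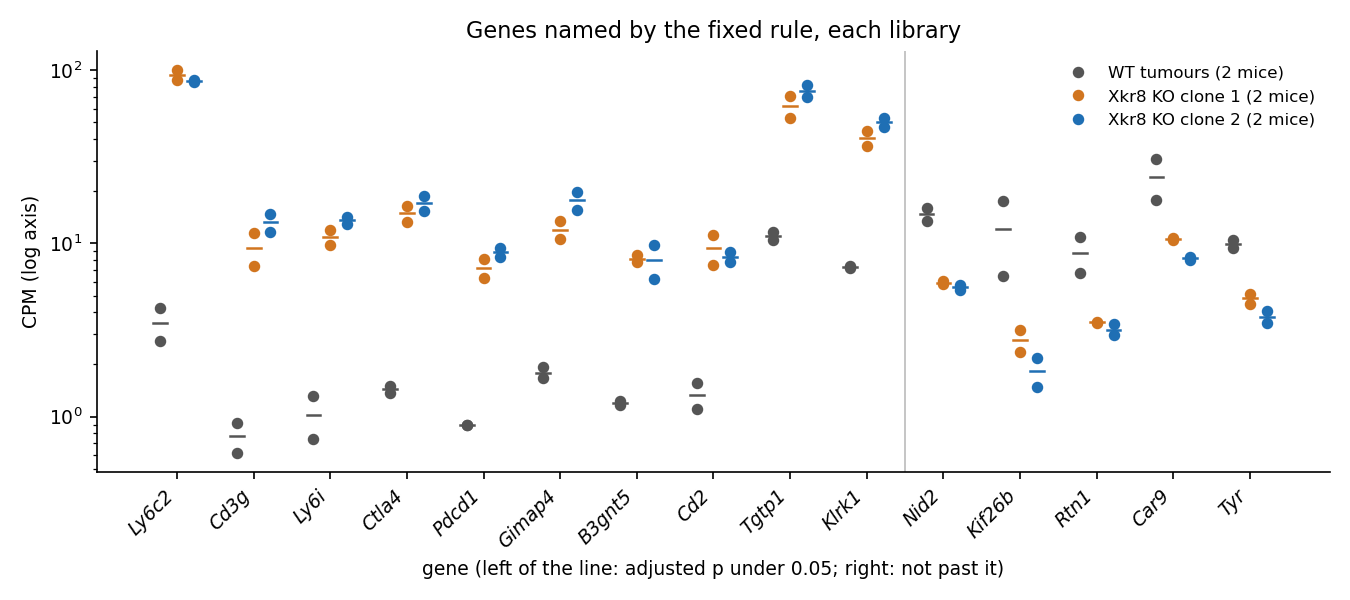
Points show the CPM of each library on a log axis for the genes chosen by the fixed rule, and short lines the mean of 2 mice. Left of the vertical line the genes passed the test with all 4 KO libraries above both WT libraries, and the 5 genes on the right are lower in all KO libraries and did not pass.

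DESeq2 called 499 genes on the same filtered counts, 360 higher and 139 lower, among them all 21, while a fit with the clones as separate groups called 1 and a fit without a filter on low counts 111. Without WT mouse 1 the count was 6020, without WT mouse 2 it was 28 (14 of them among the 21), and without any single KO library it was 1 to 4, with Ly6c2 passing each time.

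Genes of T and NK cells were higher as a list in KO libraries. Of its 27 tested members 26 had a positive log2 fold change, with a median of 2.39. 4 members were higher over all genes tested (Ctla4, Klrk1, Cd3g and Cd2), and 23 were higher when adjusted over the list alone. By camera the adjusted p was 1.32e-36, and adjusted p = 0.118 with an estimated correlation. The levels were low in absolute terms. The 3 tested Cd3 genes summed to 13.9 to 23.5 CPM in KO and to 5.01 and 7.15 CPM in WT libraries, beside 528 to 966 CPM for Adgre1. Cd3g alone stood at 7.42 to 14.9 CPM in KO and at 0.922 and 0.619 CPM in WT libraries. It thus gave much of the rise in the sum, and the other Cd3 genes together did not separate the genotypes. They were above WT mouse 1 in every KO library, but not above WT mouse 2 in clone 1 mouse 2 and clone 2 mouse 2. Cd3g was 0.619 of 7.15 CPM in WT mouse 2, 7.42 of 13.9 CPM in clone 1 mouse 2 and 11.7 of 17.7 CPM in clone 2 mouse 2. Foxp3, the regulator of regulatory T cells, was the member with a negative value (-0.67 ± 0.57).

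Interferon-stimulated genes were higher as groups in KO libraries. In the type I interferon list 41 of 43 members had positive values, with a median of 0.99. None passed over all genes tested and 34 were higher when adjusted over the list alone. The smallest p belonged to Ifi205 (2.44 ± 0.33), Ifi44 (2.12 ± 0.29) and Irf7, a transcription factor that amplifies interferon responses (1.5 ± 0.21). Bst2 and Isg15 had negative values of -0.37 ± 0.43 and -0.23 ± 0.47. Without WT mouse 2 all 43 members were positive, so the sign of these 2 genes rests on that library. In the interferon-gamma list 32 of 35 members were positive, with a median of 1.05. Tgtp1 and Upp1 (1.78 ± 0.20) passed over all genes, and 21 members were higher when adjusted over the list alone. The adjusted p was 3.41e-30 for the type I and 2.01e-23 for the interferon-gamma list, and with an estimated correlation the adjusted p = 0.104 and 0.121. The same 4 KO libraries also had higher levels of the T and NK cell and monocyte lists.

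Lists of other myeloid cell markers were also higher with the preset correlation. In the monocyte list 13 of 14 members had positive values (median 1.26), 1 passed over all genes and 5 were higher when adjusted over the list alone. Its members included Ly6c2, Plac8 (2.39 ± 0.37) and Hp, which encodes haptoglobin (2.31 ± 0.35). The list had an adjusted p of 4.18e-13, and adjusted p = 0.0483 with an estimated correlation, where it alone of the 14 passed. That value was 0.0584 without WT mouse 2 and 0.11 for the mean of the clones in the fit with 3 groups, neither of which passed. In the dendritic cell list (10 of 16 positive, median 0.65, adjusted p = 5.78e-05, and adjusted p = 0.189 with an estimated correlation) Dpp4 passed at 1.71 ± 0.22, and Ccr7, the receptor that guides cells to lymph nodes, stood at 2.70 ± 0.38. Which cells gave Dpp4 and Ccr7 was not tested, and the T and NK cell list was higher in the same libraries. The neutrophil list (11 of 13 positive, median 1.75) had an adjusted p of 5.89e-06, and adjusted p = 0.0655 with an estimated correlation. Its members Ly6g and Retnlg stayed near 1 CPM or lower in every library.

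Lists of classical and of alternative macrophage activation were both higher with the preset correlation, and neither passed with an estimated one. The T and NK cell, monocyte and dendritic cell lists were higher in the same libraries. In the M1-like list 17 of 23 members had positive values (median 0.95, adjusted p = 9.81e-08, and adjusted p = 0.0529 with an estimated correlation), with Cxcl10 at 1.08 ± 0.17 and Il12b, a subunit of IL-12, at 1.79 ± 0.33. In the M2-like list 20 of 26 were positive (median 0.86, adjusted p = 2.65e-06, and adjusted p = 0.104 with an estimated correlation), with the chemokine Ccl22 at 3.69 ± 0.53 and the lectin Mgl2 at 2.01 ± 0.30. Stab1, a scavenger receptor in the same list, stood at -0.82 ± 0.26. The costimulation list (15 of 16 positive, median 0.96, adjusted p = 1.62e-08, and adjusted p = 0.0529 with an estimated correlation) held Cd86 (1.01 ± 0.23) and Il15ra (1.04 ± 0.22). Chemokines (20 of 26 positive, median 1.13, adjusted p = 4.3e-07), nucleic acid sensing (24 of 28, 0.50, 1.12e-05) and Fc receptors and phagocytosis (17 of 24, 0.13, 0.004) were higher too. The chemokine median was 1.90 without WT mouse 1 and 0.56 without WT mouse 2, and the Fc receptor median 0.19 and 0.26. With an estimated correlation the adjusted p = 0.156 for chemokines, 0.158 for nucleic acid sensing and 0.214 for Fc receptors. Fcgr4, a receptor for IgG, stood at 1.75 ± 0.27. When adjusted over the list alone, 12 M1-like, 7 M2-like, 10 costimulation, 8 chemokine, 7 nucleic acid sensing and 5 Fc receptor genes were higher.

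Glycolysis and hypoxia genes were lower as a list in KO libraries, with 30 of 32 negative and a median of -0.52 (adjusted p = 1.37e-06, and adjusted p = 0.489 with an estimated correlation). The median was -0.24 in clone 1 and -0.86 in clone 2 against WT, so most of the value came from clone 2. Ankrd37 (-1.24 ± 0.26) and the hexokinase Hk2 (-1.29 ± 0.39) had small p, and 1 member was lower when adjusted over the list alone. Hif1a, the oxygen-sensitive transcription factor itself, had a positive value of 0.97 ± 0.28. Cholesterol synthesis genes were lower (17 of 23 negative, median -0.38, adjusted p = 0.00438, and adjusted p = 0.61 with an estimated correlation), with Srebf2, the factor that drives the pathway, at -1.17 ± 0.27. Without WT mouse 2 the glycolysis and hypoxia median was -0.33 and the cholesterol median -0.57. The cholesterol list did not pass without WT mouse 1 (adjusted p = 0.776) or without clone 1 mouse 1. Without WT mouse 1, 4 higher lists no longer passed: neutrophil (0.232), dendritic cell (0.586), M2-like (0.0646) and Fc receptors (0.186).

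The list of phosphatidylserine recognition and efferocytosis did not pass. Of its 36 tested members 16 were positive and 20 negative, and the adjusted p was 0.869. The phosphatidylserine-linked receptor kinases Mertk (0.37 ± 0.21) and Axl (-0.24 ± 0.25) did not pass. Over the alternatives Mertk ran from 0.27 to 0.48, while Axl changed sign, from -0.60 to 0.25. Lists of LXR targets and lipid handling (adjusted p = 0.644), lysosome (0.89), MHC class I (0.0557) and class II presentation (0.869), macrophage identity (0.113) and cell cycle (0.206) did not pass either. The same held for the fibroblast (0.406), endothelial (0.148) and epithelial or tumour cell lists (0.89). Several of these results rest on WT mouse 2. Without it efferocytosis (median 0.19, adjusted p = 0.00291), MHC class I (0.59, 1.41e-19), MHC class II (0.70, 3.52e-05), macrophage identity (0.27, 7.16e-05) and endothelial genes (0.70, 8.98e-05) passed as higher and cell cycle genes (-0.25, 1.09e-05) as lower. With an estimated correlation none of these 6 passed, with adjusted p of 0.0958 to 0.5. In 8 of the 23 lists that did not pass, the median, the mean and the test differed in sign, among them MHC class II and efferocytosis.

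The activation genes fixed in advance did not pass singly. Nos2 stood at -0.57 ± 0.55, Arg1 at 0.44 ± 0.24, Mrc1 at 0.11 ± 0.30, Cd274 (PD-L1) at -0.20 ± 0.46 and Tnf at 0.37 ± 0.30. Tgfb1 stood at -0.32 ± 0.28 and H2-Ab1 at 0.39 ± 0.56. Arg1 and Tnf stayed positive over the 11 alternatives, while the others changed sign. Nos2 ran from -1.22 to 0.65, Mrc1 from -0.31 to 0.69 and Cd274 from -0.72 to 0.63. Tgfb1 ran from -0.70 to 0.20 and H2-Ab1 from -0.19 to 1.41, so the direction of these 5 genes is not settled. Cxcl9 (1.12 ± 0.33, adjusted p = 0.281), Il10 (1.03 ± 0.36, adjusted p = 0.32) and Ifit1 (0.60 ± 0.20, adjusted p = 0.307) had larger values relative to their errors.

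**Figure D3:**
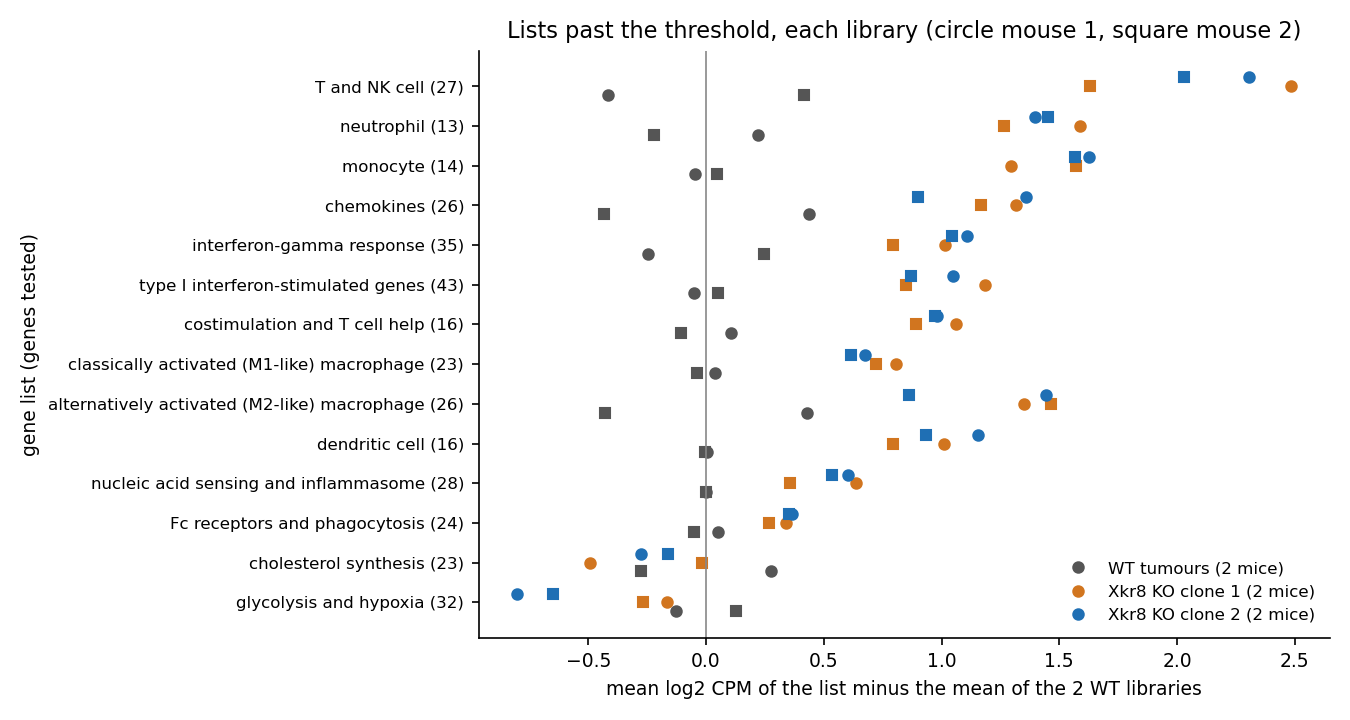
For each list that passed camera with the preset correlation, points show the mean log2 CPM of its members in each library minus the mean of the 2 WT libraries. For the 12 higher lists all 4 KO libraries lie above both WT libraries.

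A two-sided exact permutation test on the list levels of the 4 KO and 2 WT libraries gave p = 0.0667 for each of the 12 higher lists, the smallest that 15 splits allow, 0.133 for glycolysis and hypoxia and 0.467 for cholesterol synthesis. The immune checkpoint, NF-kB target and phosphatidylserine exposure lists, which did not pass camera, reached that smallest value too. The permutation test therefore does not set the 12 lists apart from these. Without WT mouse 2, 26 lists passed with the preset correlation, including all 14, and the medians of the T and NK, type I interferon and interferon-gamma lists were 2.85, 1.01 and 1.2. With an estimated correlation none passed without it, and these 3 lists had an adjusted p of 0.0957.

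Each KO clone was then set against WT to ask whether either clone alone showed the difference. Ly6c2 was the single gene past the threshold in both. It was higher by 4.77 ± 0.31 in clone 1 (adjusted p = 0.0302) and by 4.66 ± 0.30 in clone 2 (adjusted p = 0.0342). Ctla4 stood at 3.37 ± 0.28 in clone 1 and 3.56 ± 0.29 in clone 2, and Tgtp1 at 2.48 ± 0.25 and 2.78 ± 0.25, with adjusted p of 0.0501 to 0.082. Among genes that met the criteria of level and separation for naming, Lrrc17 (-2.91 ± 0.29) and Thbs2 (-1.96 ± 0.22) had the lowest p for a negative value in clone 1. Mme (-4.35), Col11a1 (-3.09) and Aspn (-3.81) followed. In clone 2 the lowest p among such genes belonged to the inducible heat shock proteins Hspa1b (-2.91 ± 0.29) and Hspa1a (-2.82 ± 0.31), near-copies of each other. Fbln2 (-3.00), Adamts9 (-2.13) and Gadd45a (-1.93) came next. None of these 10 genes passed, with adjusted p of 0.0524 to 0.179.

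At an unadjusted p under 0.05, 1104 genes differed in clone 1 and 1756 in clone 2. DESeq2 called 271 and 465 genes. Without WT mouse 2 the counts were 58 and 186, without WT mouse 1 they were 5535 and 6445, and without any single KO library they were 0.

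The 2 clones carry the same genotype, and their contrast tests whether their effects differ. Clone 2 libraries had less glycolysis and hypoxia expression than clone 1 libraries, with 31 of 32 members negative and a median of -0.49 (adjusted p = 2.47e-12, and adjusted p = 0.942 with an estimated correlation). Adm, a peptide induced by low oxygen (-2.15 ± 0.36), the glucose transporter Slc2a1 (-0.90 ± 0.26) and Ero1l (-0.98 ± 0.29) were among them. MHC class II genes were higher in clone 2, with 14 of 14 members positive and a median of 0.77 (adjusted p = 2.9e-09, and adjusted p = 0.942 with an estimated correlation). H2-Ab1 (1.24 ± 0.51), H2-Aa (1.37 ± 0.52) and their master regulator Ciita (1.07 ± 0.44) belong here. Interferon-gamma response genes were higher (27 of 35 positive, median 0.29, adjusted p = 0.000905), with Cxcl9 at 0.80 ± 0.24, and matrix remodelling genes were lower (21 of 31 negative, median -0.25, adjusted p = 0.0277), with Adam8 at -1.21 ± 0.32 and, against the list, Lox at 3.73 ± 0.55. Both had an adjusted p = 0.942 with an estimated correlation.

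The matrix list lost its call without clone 1 mouse 2 and without clone 2 mouse 1, and the interferon-gamma list without clone 1 mouse 2. When adjusted over the list alone, Adm was lower and Lox and the growth factor Hbegf (-1.23 ± 0.26) passed in the matrix list, while no MHC class II or interferon-gamma gene did. WT mouse 2, with 2206 CPM of H2-Ab1, lay nearer to clone 2 (2660 and 2712 CPM) than to clone 1 (994 and 1274 CPM), and WT mouse 1 had 708 CPM.

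No single gene passed between the clones with edgeR's quasi-likelihood test, and the smallest adjusted p was 0.181. At an unadjusted p under 0.05 the count was 502, DESeq2 called 117 genes and limma-voom 0. Among genes that met the criteria of level and separation, those with the smallest p are given. Higher values in clone 2 belonged to the matrix proteoglycan Aspn (4.96 ± 0.64), Dlc1 (2.17 ± 0.28), the keratin Krt14 (4.08 ± 0.54), Thbs2 (1.62 ± 0.21) and Cdon (1.94 ± 0.26). Lower values belonged to the adhesion molecule Ncam1 (-2.0 ± 0.21), Adamts9 (-2.54 ± 0.32), Vipr2 (-2.68 ± 0.35), Rbms3 (-2.0 ± 0.26) and Fbln2 (-2.50 ± 0.33). Without WT mouse 1 or WT mouse 2, which enter through the shared spread, the counts were 78 and 87.

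Across 15560 genes the log2 fold changes of the 2 clones against WT had a Pearson correlation of 0.74 and a Spearman correlation of 0.782, and 82.8% had the same sign. Both clones were compared with the same WT libraries. Simulated clones without any change were compared with shared, simulated WT libraries. They gave a Pearson correlation of 0.524 (0.493 to 0.554 in 100 draws), a Spearman correlation of 0.482 and 67.1% with the same sign. All simulated libraries were drawn from the same mean and spread for each gene. They therefore do not show what a WT library that stands apart, such as WT mouse 2, adds to these values. The covariance was 0.457, against 0.16 in the simulations over the same genes. It was 2.94 without WT mouse 1, 0.416 without WT mouse 2 and 0.262 for genes of at least 5 CPM, settings that were not simulated. Genes are not independent replicates, and with 2 WT libraries the controls were not split, since that leaves 1 WT library for each clone, so part of the excess may come from the shared controls.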

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

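The tests without WT mouse 2 in this part were chosen after that library had been seen to stand apart.

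T and NK cell transcripts were higher in KO libraries, with a median log2 fold change of 2.39 over 27 genes. The level of this list (mean log2 CPM) was 0.15 in WT mouse 1, 0.98 in WT mouse 2 and 2.20 to 3.05 in KO libraries. WT mouse 2 alone is thus not the source of this difference, since it lay nearer to the KO libraries than WT mouse 1 did. For that reason leaving it out was likely to raise the difference, whatever the cause. The median without it was 2.85 with all 27 members positive, against a lone WT library. A second list of 32 T and NK cell genes, with no member in the fixed lists and written before its values were seen, had a positive log2 fold change in 30 of 31 tested members and a median of 1.73, as T or NK cells among the sorted cells would give. No member passed over all genes tested, and the smallest adjusted p was 0.0561 (Klrc1). Its 3 most abundant members were Ly9 (28.1 and 44.4 CPM in WT, 55.5 to 75.1 CPM in KO), Il7r (29.9 to 95.9 CPM over all libraries) and Grap2 (37 to 64.8 CPM). Of these, Grap2 hardly differed between genotypes, with a log2 fold change of -0.11 ± 0.25. Il7r had a value of 0.10 ± 0.48 because the clones lay on opposite sides of WT. It stood at 57.8 and 42.6 CPM in WT, 95.9 and 58.5 CPM in clone 1 and 30.4 and 29.9 CPM in clone 2. A larger share of carried-over lymphocytes in KO tumours may account for these transcripts, whatever the gate, which the labels do not give. Whether macrophages held this RNA, and whether the tumours differed in infiltrate, was not tested.

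Ly6c2 and the interferon-stimulated genes were higher in KO libraries. The level of the type I interferon list (mean log2 CPM) was 6.31 in WT mouse 1, 6.41 in WT mouse 2 and 7.21 to 7.55 in KO libraries. WT mouse 2 alone thus does not account for the pattern in this list. With the WT libraries this close, leaving it out could hardly change the result, and the median without it was 1.01 against a lone WT library. A second list of 20 monocyte genes had a positive log2 fold change in 17 of 19 tested members and a median of 1.13, as a larger share of monocytes or of recently arrived macrophages among the sorted cells would give. No member passed over all genes tested, and the smallest adjusted p was 0.0637 (Gpr141). It shares 3 genes with the fixed lists, and Ccr2 among them had been seen, but the 16 tested genes in no fixed list had a median of 1.16. Without WT mouse 2 the median of the second list was 0.65, so part of its rise rests on that library. Ccr2 stood at 277 CPM in WT mouse 1, 40.6 CPM in WT mouse 2 and 281 to 717 CPM in KO libraries. Vcan stood at 287, 151 and 196 to 250 CPM in the same order, and Klra2 at 127, 73.9 and 203 to 300 CPM. No member rose as much as Ly6c2 taken alone (4.72), and the largest log2 fold change was 2.76 (Cd177). Because the split of reads between Ly6c1 and Ly6c2 is uncertain, this comparison is uncertain too. Their summed level, 19.0 and 16.8 CPM in WT and 98.2 to 129 CPM in KO libraries, rose less than Ly6c2 alone. A changed cell mixture may contribute to Ly6c2, while a change of state within macrophages from KO tumours stays open and was not tested.

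WT mouse 2 stood apart from the other 5 libraries. Lower depth is argued against, since the other 5 thinned to its 15100967 reads outside Rn45s had a median correlation of 0.975 with each other, above its highest of 0.919 with any of them. Across 14910 genes its deviation from the other libraries had a Spearman rho of 0.473 with GC content, the largest absolute value of the 6 libraries, so a bias with GC content may be part of it. Genes with no count in it and at least 10 CPM in all others after thinning numbered 5 of 8830, against 0 for any other library, too few to tell whether little starting RNA was the cause. No biological explanation was tested, and a difference between the mice stays open.

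The count of 21 genes between genotypes was set against the other ways of dividing the 6 libraries into 2 and 4. There are 15 divisions, too few for a share under 0.05. The real one gave 21 genes, 2 of the 15 gave as many with the real one included, and the highest of the others was 81, with WT mouse 2 and clone 1 mouse 1 on one side. That division calls several times the real count, so the count does not single out the division by genotype. The other divisions with WT mouse 2 and 1 KO library on one side gave 0 to 4 genes. What lies behind the 81 was not tested.

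The clones differed by the list test in 4 lists, with adjusted p of 2.47e-12 for glycolysis and hypoxia, 2.9e-09 for MHC class II presentation, 0.000905 for the interferon-gamma response and 0.0277 for matrix remodelling. Each had an adjusted p = 0.942 with an estimated correlation.

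Single KO libraries lay far from the other 3 in 6 of 88 values examined, where chance gives about 1 in 20. The gap to the nearest library, as a share of the whole range of the 4, was 0.963 for the macrophage identity list, 0.928 for B and plasma cell genes, 0.874 for Csf1r and 0.841 for sex-linked genes, each lowest in clone 1 mouse 2. It was 0.921 for the symbols with counts, highest in clone 1 mouse 1 (18865), and 0.831 for the Rn45s share, highest in clone 2 mouse 1 (7.12%).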

How the results depend on the processing

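Of the alternatives below, limma-voom with sample quality weights and leaving out libraries in the list test between clones were chosen after seeing the data. The count of genes between genotypes was 21, and near it with RLE size factors (18), limma-voom (16), the stricter filter (14) and without Rn45s (21). It was 499 with DESeq2, 111 without a filter, 1 in the fit with 3 groups and 1 with quality weights, and ran from 1 to 6020 when single libraries were left out. For clone 1 against WT the count of 1 became 271 with DESeq2, 123 without a filter, 0 with the stricter filter and 2 with quality weights, and 0 to 5535 without single libraries. For clone 2 against WT it became 9 with RLE factors (8 higher, 1 lower), 465 with DESeq2, 229 without a filter, 0 with the stricter filter and 4 with quality weights, and 0 to 6445. Between clones the count of 0 became 117 with DESeq2, 53 without a filter and 210 with quality weights, and 0 to 87. The 14 lists between genotypes became 1 with an estimated correlation and 11 to 26 without single libraries, and the 4 lists between clones 0 and 4 to 13. The correlation of the clones was 0.83 for genes of at least 5 CPM and 0.65 to 0.932 without either WT library. Leaving out a WT mouse leaves a lone WT library, assumed to vary like the other groups. The highest counts against WT came without WT mouse 1, where the lone library is WT mouse 2, which stood apart from the others. Apart from that, the cause was not tested.

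Between clones, 3 lists that did not pass passed in opposite directions depending on which clone 1 library was left out. Without clone 1 mouse 1 and without clone 1 mouse 2, the medians were -0.25 and 0.24 for cholesterol synthesis (0.02 with all libraries), -0.21 and 0.21 for ribosomal proteins (-0.02), and -0.36 and 0.30 for the histones (-0.09). Ly6c2 passed between genotypes under all 11 alternatives run for it, with adjusted p of up to 0.0481.

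The mouse numbers are shared by the groups, but the differences of mouse 1 and mouse 2 correlated at -0.135, 0.05 and 0.197 between groups, so they are taken as numbers only. With the replicate block the count between genotypes was 15 (11 among the 21), each clone against WT 0, between clones 0, and 15 and 4 lists passed.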

Other observations

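The inducible heat shock genes Hspa1a and Hspa1b had their lowest values in clone 2. In clone 2 against WT neither passed in the main test (adjusted p = 0.0524 for Hspa1b and 0.0794 for Hspa1a), while Hspa1b passed under 5 and Hspa1a under 4 of 10 alternatives. Hspa1a stood at 662 and 384 CPM in WT libraries, 247 and 270 CPM in clone 1 and 74.9 and 72.9 CPM in clone 2. Hspa1b followed the same order, with adjusted p between genotypes of 0.32 and 0.282. Among vascular genes, Pecam1 (1.48 ± 0.19, adjusted p = 0.0525) and Flt1 (1.84 ± 0.29, adjusted p = 0.0675) had higher values in KO libraries, while Cdh5 (0.16 ± 0.48) and Vwf (-0.92 ± 0.46) did not follow. These genes were picked after their values were seen.

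Fibrillar collagen transcripts were unequal between libraries, and of those given here only Col3a1 was abundant throughout. Col3a1 stood at 1837 to 3634 CPM in 5 libraries and at 11320 CPM in WT mouse 2, while Col1a1 stood at 12.2 to 70.2 CPM in the 5 and 291 CPM in WT mouse 2. Lox, a collagen crosslinking enzyme, was at 64.7 and 65.9 CPM in clone 2 libraries and 3.1 to 14.4 CPM in the other 4. The haemoglobin gene Hbb-b1 was highest in WT mouse 1 (34.5 CPM, against 1.79 to 6.98 CPM in the others). Without WT mouse 2 it was the single gene lower in KO libraries, with a log2 fold change of -2.73 ± 0.23.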
